A study of Arabidopsis thaliana with 141 samples.

How the data were processed

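Total RNA came from 7-d-old seedlings grown in liquid medium, 8 seedlings pooled per RNA, and from shoots of 4-week-old soil-grown plants, under 12 h light and 12 h dark. In the time course WT seedlings received 100 nM flg22 for 5, 10, 15, 30 or 60 min, with water at 0 min. In sets B1 to B4 seedlings were pretreated for 15 min with 0.1% DMSO or 10 uM 3MBiP and then received 2 nM flg22, 100 nM pep3, 20 uM abscisic acid, 50 uM methyl jasmonate, wounding by forceps, UVB (40 W in the labels) or 10 mM H2O2. The labels give 1 h of incubation for the stimuli, but 30 min in the names of 3 flg22 groups. Adult plants received a spray of 3MBiP (100 uM) or, as mock, DMSO (1%) and were taken 3, 6, 12 or 24 h later, with an untreated 0 h group and untreated mpk4 plants.

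The authors deposited raw read counts per gene locus, 1 library per file, made per their processing notes with HTSeq after TopHat alignment to TAIR10. Versions and settings are not stated. The values are whole numbers and were taken as counts without normalisation. Files of the time course, B1, B2 and B3 list 32678 loci and those of B4 and the adult set 37336. Each set was fitted alone, and no gene was tested between libraries of different sets. Correlations across genes, the overlap between seedling sets, a gene list from the time course and a seedling level used for adult libraries do join sets. That seedling level is the mean CPM of unstimulated WT seedlings of B4, which received 3MBiP. It was normalised apart from the adult set. Counts assigned to genes ranged from 13.9 to 40.4 M per library, alignments that were not unique from 5.38 to 42.4% and reads in no feature from 0.83 to 2.30%. Reads carry no molecular identifiers, and the lower bounds given for genes with few counts cover counting error only. Values after ± also hold the spread between libraries. Symbols and coordinates come from the TAIR10.1 annotation, which held 31912 of the 32678 loci and 37051 of the 37336.

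Groups follow the labels, and each of the 6 sets was fitted with 1 mean per group in edgeR 4.0.16 (R 4.3.3) after filterByExpr by group, with TMM normalisation, robust quasi-likelihood dispersions and two-sided quasi-likelihood F tests. Between 20806 and 21543 genes were tested per set. The common biological coefficient of variation was 0.047 in the time course, 0.078 in B1, 0.057 in B2, 0.082 in B3, 0.069 in B4 and 0.12 in the adult set. P values were adjusted by Benjamini-Hochberg within each of the 40 comparisons, and genes with adjusted p under 0.05 were counted. Interactions subtract the WT response from that of the mutant. Mock times were compared by an F test over 5 groups. Whether replicate numbers pair libraries was read from the correlation of their deviations from the group means, since the labels name no shared origin. All 3 pairs correlated above 0.1 in 4 planned comparisons of 2 groups, which were taken as paired. These were impk36 with WT at baseline in B2 (lowest r 0.17) and with H2O2 (0.16), impk4 with WT after UVB (0.28), and adults at 6 h (0.14). The added comparison of impk36 with WT after 1 h of flg22 (0.19) did so too. Reported counts and values come from fits without the pairing. With replicate number as a block the 4 counts were 7188, 2632, 292 and 988, against 6655, 2377, 147 and 1266. In the whole adult set 27.4% of same-numbered library pairs and 27.8% of the others passed 0.1, so pairing at 6 h may be chance. With 3 libraries against 3, the groups fail to overlap in 10% of unchanged genes by chance, and an exact permutation p cannot go below 0.1, so single genes rest on the model's pooled spread.

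The 19 gene lists (330 members) were fixed before the data were examined. They cover pattern-triggered immunity, early transcription factors, the MAPK cascade, salicylic acid, jasmonate, abscisic acid, touch and calcium, UVB and flavonoids, oxidative stress and detoxification, heat and chaperones, indole defence, ethylene, auxin and growth, photosynthesis, the clock, NLR receptors, senescence, and root and floral markers for organs the shoots should lack. The root markers SCR, SHR and GL2 were nonetheless present in all adult mock groups. Lists were tested with limma 3.58.1 camera on voom values with an estimated correlation between genes, two-sided, adjusted over the lists of a comparison. A list call therefore says that its genes moved relative to other genes. The flg22 list holds 982 genes with adjusted p under 0.05 and a log2 fold change of at least 2 at both 30 and 60 min of the time course. It was tested in B1 to B4, whose libraries did not choose it, with its own p.

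Named genes follow a rule also fixed then. List members are taken in order of adjusted p, with MPK3, MPK6 and MPK4 throughout. To these come up to 10 genes per direction ranked by fold change with adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the libraries compared. Ranked genes with a symbol were preferred, and those with 3 or fewer counts in the lower group were left out or given as a lower bound on 3 counts over that group. For interactions no log ratio of a stimulated mutant library to the mean of its controls may overlap those of WT. The CPM levels of single clock and marker genes were chosen for the text after their values were seen.

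Alternatives fixed in advance were DESeq2 size factors in place of TMM, no filter on low counts, the DESeq2 1.42.0 Wald test, replicate number as a block, a fit to the compared groups alone, and leaving out each library in turn. For the lists a preset correlation of 0.01, the block and DESeq2 size factors were tried, and for the flg22 list other fold thresholds. Correlations across genes were repeated over called genes and over genes of at least 5 CPM. Added after seeing the data were the mutants against WT among stimulated libraries, mpk4 against the 6 h mock, the adult comparisons over genes not above the mock level in seedlings, and the adult lists without a control library that stands apart from its group. The pipeline was tested on simulated data with 100 genes changed 1.5-fold and 100 changed 3-fold in 6 comparisons. It recovered 70 to 98 of the former and 98 to 100 of the latter, with 6 to 17 wrong calls. Seedling mutants were all in 3MBiP, no stimulus was given in DMSO, and in B3 and B4 no mutant group lacked the stimulus, so mutants were compared directly with WT there.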

Results

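RNA was sequenced from 141 libraries of Arabidopsis thaliana in 49 groups. The first part of the series followed 7-d-old wild-type (WT) seedlings for up to 60 min after 100 nM flg22, a peptide of bacterial flagellin, with 2 libraries per time point. The second part held 4 seedling sets, B1 to B4 in the labels, of WT, impk36 and impk4 seedlings given the inhibitor 3MBiP (10 uM) and then a stimulus, with 3 libraries per group. The third part held shoots of 4-week-old impk4 plants sprayed with 100 uM 3MBiP or 1% DMSO (mock), and shoots of mpk4 plants, also with 3 libraries per group. MPK3, MPK6 and MPK4 are mitogen-activated protein kinases of the immune signalling cascade, and the labels name impk36 and impk4 without describing the lines. Counts assigned to genes ran from 13.9 to 40.4 M per library, with a median of 23.5 M. A value written a ± b is a log2 fold change with a standard error computed here from edgeR's F statistic (fold change over its square root). It rests on 3 libraries per group unless the flg22 time course (n = 2) is named. Levels are given in CPM (normalised counts scaled to library size) ± SD.

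The kinases named in the lines were read first. In unstimulated set B1 seedlings, MPK6 (AT2G43790) stood at 308.2 ± 28.6 CPM in impk36 and 58.6 ± 1.33 in WT (n = 3 each), and MPK3 (AT3G45640) at 16.9 ± 1.55 against 60.5 ± 5.29. MPK4 (AT4G01370) stood at 1496 ± 39.6 CPM in impk4 against 61.6 ± 0.843 in WT. The same directions held in the other comparisons of lines, among them MPK6 (2.39 ± 0.05) and MPK3 (-1.66 ± 0.11) in impk36 with UVB, and MPK4 (4.52 ± 0.05) in impk4 with H2O2. In TAIR10.1, MPK6 lies on chromosome 2 at 18138246 to 18140988, MPK3 on chromosome 3 at 16756571 to 16758874, and MPK4 on chromosome 4 at 566917 to 570299. In adult shoots MPK4 was at 1503 ± 57.1 CPM in untreated impk4 and 22.5 ± 2.14 in mpk4. The impk4 line also held little transcript of EHD1 (AT3G20290, -5.24 ± 0.10), on chromosome 3 at 7074764 to 7079014, and less ATM1 (AT3G19960, -0.99 ± 0.07), a myosin gene at 6948774 to 6957726 of the same chromosome. Both were lower in impk4 in all 4 seedling sets.

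**Figure D1:**
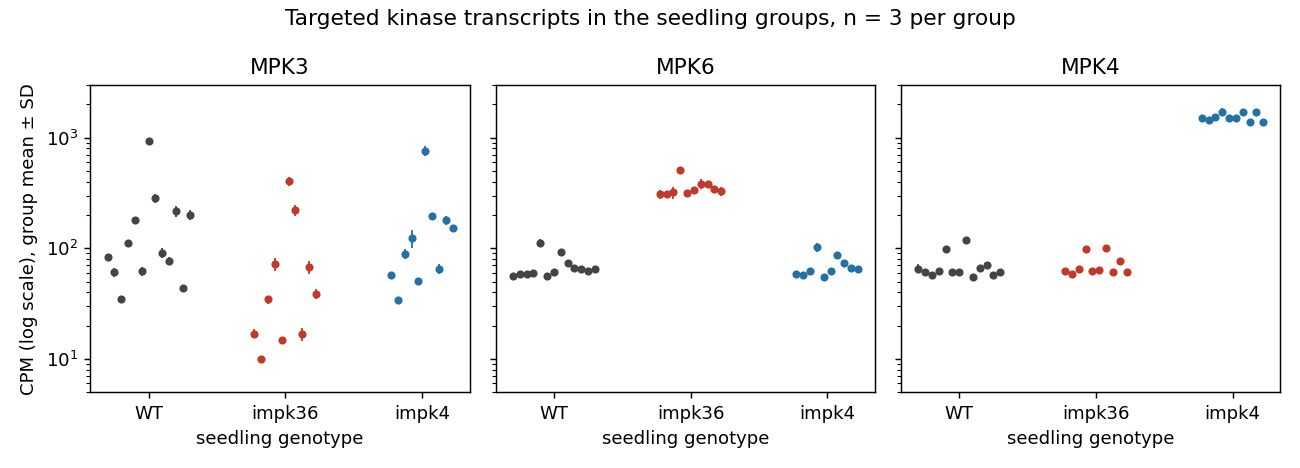
Normalised CPM (log axis, group mean ± SD, n = 3) of MPK3, MPK6 and MPK4 in each group of the 4 seedling sets, by line. MPK6 lay near 308.2 CPM in unstimulated impk36 of set B1 and MPK4 near 1496 CPM in impk4, against 58.6 and 61.6 CPM in WT.

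The time course asked how early WT seedlings respond to flg22. Its only control was water at 0 min, so effects of handling or elapsed time cannot be told from those of flg22. The flg22 list chosen from these libraries shares this limit. After 5 min 201 of 20871 genes (103 higher and 98 lower) differed from 0 min. STZ (AT1G27730, 1.59 ± 0.11), a zinc finger repressor of stress responses, led the rise, followed by CAF1a (AT3G44260, 1.23 ± 0.09), a subunit of the complex that shortens mRNA tails, and ERF5 (AT5G47230, 0.95 ± 0.12), an ethylene response factor. Marneral synthase MRN1 (AT5G42600, -1.19 ± 0.10) and WRKY70 (AT3G56400, -0.70 ± 0.12), a regulator of salicylic acid responses, were among those that fell. Of the early transcription factors, 7 of 21 rose and 0 fell (11 and 2 adjusted over the list alone, median 0.32, adjusted p = 0.24 with an estimated correlation). At 10 min 21 of 21 rose and 0 fell (21 and 0 adjusted over the list alone, median 3.42, adjusted p = 0.0049 with an estimated correlation) of the same list, with SZF1 (AT3G55980, 2.82 ± 0.07), WRKY40 (AT1G80840, 4.30 ± 0.09) and ERF5 (4.71 ± 0.10) as examples. Pattern-triggered immunity genes followed, as 13 of 18 rose and 0 fell (16 and 0 adjusted over the list alone, median 1.47, adjusted p = 0.018 with an estimated correlation) at 10 min. Changed genes numbered 2040 at 10 min (1320 higher and 720 lower) and 4557 at 15 min (2626 higher and 1931 lower). Genes of UVB response and flavonoid synthesis moved the other way at 10 min. Of the whole list 0 of 16 rose and 8 fell (1 and 12 adjusted over the list alone, median -0.36, adjusted p = 0.018 with an estimated correlation). The count at 5 min was 39 without replicate 1 of 0 min, 443 without its replicate 2, and 95 and 51 without replicates 1 and 2 of 5 min. At 10 min it was 1205 without replicate 1 of 0 min. Without a filter on low counts 734 genes differed at 5 min.

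At 30 min 8903 of 20871 genes (4617 higher and 4286 lower) had changed. A cytochrome P450 gene with 0 counts at 0 min, CYP82C3 (AT4G31950, at least 11.64), headed the ranking at this lower bound. Pattern-triggered genes included WRKY33 (AT2G38470, 5.95 ± 0.08), a regulator of camalexin synthesis, RBOHD (AT5G47910, 4.27 ± 0.07), the oxidase of the immune oxidative burst, and the flg22-responsive WRKY22 (AT4G01250, 4.200 ± 0.07). In that list 17 of 18 rose and 0 fell (18 and 0 adjusted over the list alone, median 4.16, adjusted p = 0.039 with an estimated correlation). Salicylic acid genes had joined, since 15 of 22 rose and 1 fell (15 and 1 adjusted over the list alone, median 2.199, adjusted p = 0.039 with an estimated correlation), among them SAG101 (AT5G14930, 3.26 ± 0.07) and SARD1 (AT1G73805, 5.82 ± 0.13). MPK3 itself reached 1293 ± 8.95 CPM at 30 min from 60.2 ± 1.91 at 0 min, and stood at 611.1 ± 13.3 at 60 min. B-box gene BBX15 (AT1G25440, -3.39 ± 0.10) was among the strongest falls, with MAKR6 (AT5G52900, -3.36 ± 0.17) and the cytokinin response regulator ARR6 (AT5G62920, -3.22 ± 0.13).

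By 60 min 13824 of 20871 genes (6817 higher and 7007 lower) differed from 0 min. Genes of indole glucosinolate and camalexin synthesis were high, as 13 of 17 rose and 1 fell (13 and 2 adjusted over the list alone, median 3.06, adjusted p = 0.17 with an estimated correlation), led by IGMT2 (AT1G21120, 7.88 ± 0.09) and MYB51 (AT1G18570, 5.60 ± 0.08). All 19 measured photosynthesis genes fell (19 adjusted over the list alone, adjusted p = 0.17 with an estimated correlation), with LHCB2.1 (AT2G05100, -1.65 ± 0.06) first. Of the early transcription factors 17 of 21 rose and 2 fell (17 and 2 adjusted over the list alone, median 2.90, adjusted p = 0.13 with an estimated correlation) at this time. Resistance (NLR) receptor genes rose, ZAR1 (AT3G50950, 3.04 ± 0.07) and ADR1-L1 (AT4G33300, 2.11 ± 0.06) among them. Of the list's genes 12 of 14 rose and 0 fell (12 and 0 adjusted over the list alone, median 1.97, adjusted p = 0.13 with an estimated correlation). Lists whose p with an estimated correlation exceeded 0.05 were not told apart from other genes at that time, although most members passed singly.

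**Figure D2:**
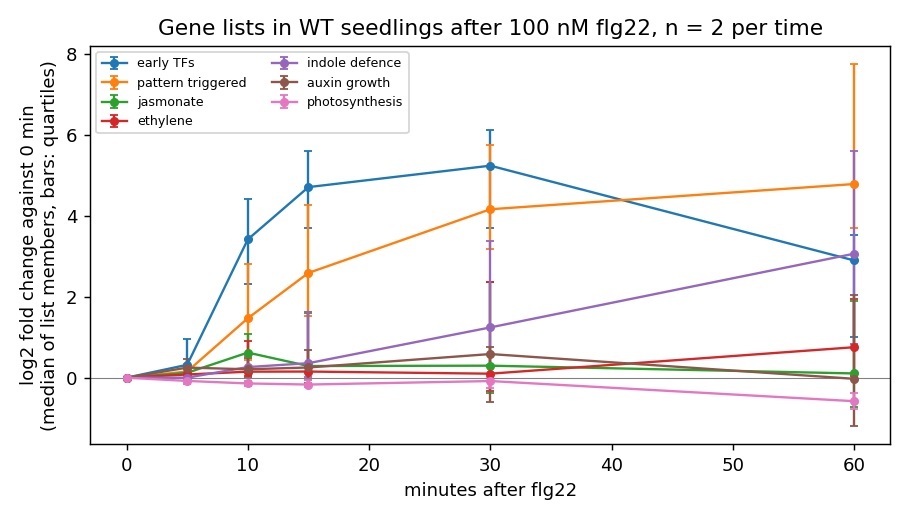
Log2 fold change against 0 min of 7 gene lists over minutes after 100 nM flg22 in WT seedlings (median of list members with quartiles, n = 2 libraries per time). The median of the early transcription factors was 3.42 at 10 min, and that of pattern-triggered genes 4.16 at 30 min.

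The inhibitor alone was compared with DMSO in WT seedlings of set B1. There 1834 of 21211 genes (979 higher and 855 lower) differed. ERF53 (AT2G20880, 4.68 ± 0.52), a drought-linked transcription factor, and the auxin-conjugating enzyme GH3.3 (AT2G23170, 3.49 ± 0.25) rose most, and NAC6 (AT5G39610, -1.75 ± 0.15), a senescence regulator, fell. Auxin and growth genes moved up, as 6 of 14 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.68, adjusted p = 0.00086 with an estimated correlation), with the expansin EXPA1 (AT1G69530, 1.56 ± 0.11) and IAA2 (AT3G23030, 1.04 ± 0.09). Detoxification genes did too, where 10 of 18 rose and 0 fell (12 and 2 adjusted over the list alone, median 0.38, adjusted p = 0.0012 with an estimated correlation), such as GSTU1 (AT2G29490, 0.99 ± 0.10). Ethylene genes went down, as 0 of 16 rose and 6 fell (3 and 7 adjusted over the list alone, median -0.20, adjusted p = 0.033 with an estimated correlation), and ACS7 (AT4G26200, -1.40 ± 0.16), an enzyme of ethylene synthesis, was first among them. In the pattern-triggered list 1 of 17 rose and 8 fell (1 and 11 adjusted over the list alone, median -0.65, adjusted p = 0.033 with an estimated correlation). The count was 1095 without replicate 2 of DMSO and 1186 without its replicate 3. All further seedling comparisons were made between libraries that had received 3MBiP.

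Abscisic acid (20 uM) changed 6454 of 21211 genes (3539 higher and 2915 lower) in WT seedlings. In the abscisic acid list 27 of 30 rose and 3 fell (27 and 3 adjusted over the list alone, median 3.22, adjusted p = 0.0083 with an estimated correlation). The 3 that fell were receptors of the hormone, PYL4 (AT2G38310, -4.33 ± 0.06), PYL5 (AT5G05440, -3.03 ± 0.11) and PYL6 (AT2G40330, -6.66 ± 0.28), while the desiccation genes RD20 (AT2G33380, 6.99 ± 0.15) and RAB18 (AT5G66400, 5.75 ± 0.35) and the phosphatase HAB1 (AT1G72770, 3.29 ± 0.12) rose. NAC019 (AT1G52890, 7.51 ± 0.37) had the highest change. Senescence genes rose as well, NYE1 (AT4G22920, 1.53 ± 0.08) of chlorophyll breakdown among them. In this list 8 of 9 rose and 0 fell (8 and 0 adjusted over the list alone, median 1.17, adjusted p = 0.0042 with an estimated correlation). Among detoxification genes 12 of 18 rose and 0 fell (15 and 1 adjusted over the list alone, median 0.60, adjusted p = 0.00058 with an estimated correlation), for instance AOX1A (AT3G22370, 1.98 ± 0.11), the alternative oxidase. Methyl jasmonate (50 uM) changed 6827 of 21211 genes (3405 higher and 3422 lower). The jasmonate list rose whole, as 25 of 25 rose and 0 fell (25 and 0 adjusted over the list alone, median 5.05, adjusted p = 0.00056 with an estimated correlation), among them OPCL1 (AT1G20510, 5.05 ± 0.10) and OPR3 (AT2G06050, 4.96 ± 0.13) of jasmonate synthesis and the repressor JAZ10 (AT5G13220, 7.93 ± 0.15). Indole defence genes rose with ASA1 (AT5G05730, 3.26 ± 0.09) and TSB2 (AT4G27070, 2.69 ± 0.09) of tryptophan synthesis. Of the whole list 10 of 17 rose and 2 fell (12 and 2 adjusted over the list alone, median 2.08, adjusted p = 0.011 with an estimated correlation). FAMT (AT3G44860, 11.05 ± 0.48) and TAT3 (AT2G24850, 10.70 ± 0.38) ranked among the highest and BAT1 (AT4G31910, -2.93 ± 0.14) among the lowest.

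Pep3 (100 nM), an endogenous danger peptide, changed 13261 of 21211 genes (6823 higher and 6438 lower) within 1 h. The flg22 list, 982 genes chosen here on the time course libraries for a rise of at least 2 on the log2 scale at 30 and 60 min, was tested on the B sets, which did not choose it. In it 913 of 927 rose and 1 fell (916 and 1 adjusted over the list alone, median 2.99, p = 1.1e-06 with an estimated correlation). Pattern-triggered genes rose, BAK1 (AT4G33430, 1.96 ± 0.05), a co-receptor of immune receptors, and WRKY33 (4.60 ± 0.12) first. Of the list's genes 17 of 17 rose and 0 fell (17 and 0 adjusted over the list alone, median 2.802, adjusted p = 0.0053 with an estimated correlation). For ethylene genes 14 of 16 rose and 0 fell (14 and 1 adjusted over the list alone, median 1.39, adjusted p = 0.0071 with an estimated correlation), with ACS7 (3.84 ± 0.15), and for salicylic acid genes 17 of 21 rose and 1 fell (18 and 1 adjusted over the list alone, median 1.69, adjusted p = 0.0077 with an estimated correlation), with CBP60G (AT5G26920, 5.24 ± 0.16). Cascade kinases followed in part, as 20 of 23 rose and 1 fell (20 and 1 adjusted over the list alone, median 1.44, adjusted p = 0.025 with an estimated correlation), for instance MEKK3 (AT4G08470, 2.27 ± 0.08) and MPK11 (AT1G01560, 5.91 ± 0.22). Touch and calcium genes included TCH3 (AT2G41100, 5.74 ± 0.12). In this list 6 of 7 rose and 0 fell (6 and 0 adjusted over the list alone, median 2.09, adjusted p = 0.047 with an estimated correlation). DES1 (AT5G28030, -4.05 ± 0.24) and CYP79F1 (AT1G16410, -3.89 ± 0.23), an enzyme of aliphatic glucosinolate synthesis, fell most.

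With 2 nM flg22, 9162 of 21223 genes (4688 higher and 4474 lower) had changed in WT at 30 min and 12818 of 21223 genes (6317 higher and 6501 lower) at 1 h. At 30 min the flg22 list rose nearly whole, where 942 of 967 rose and 1 fell (945 and 2 adjusted over the list alone, median 3.65, p = 6.6e-05 with an estimated correlation), and at 1 h 951 of 967 rose and 1 fell (954 and 1 adjusted over the list alone, median 3.77, p = 0.00097 with an estimated correlation). PHI-1 (AT1G35140, 5.92 ± 0.09) and WRKY53 (AT4G23810, 7.07 ± 0.14) led the pattern-triggered genes at 30 min, of which 17 of 17 rose and 0 fell (17 and 0 adjusted over the list alone, median 5.16, adjusted p = 0.0073 with an estimated correlation). Early factors such as ERF104 (AT5G61600, 5.05 ± 0.09) and ERF5 (6.82 ± 0.12) were high at 30 min. Of the whole list 20 of 22 rose and 1 fell (21 and 1 adjusted over the list alone, median 5.001, adjusted p = 0.0073 with an estimated correlation). At 1 h salicylic acid genes counted 18 of 21 higher and 1 lower (18 and 1 adjusted over the list alone), with adjusted p = 0.037 with an estimated correlation, and photosynthesis genes 0 of 19 higher and 17 lower (0 and 17 adjusted over the list alone), with adjusted p = 0.18 with an estimated correlation. EXPA1 (-4.02 ± 0.15) and BBX14 (AT1G68520, -4.27 ± 0.18) were among the strongest falls at 1 h.

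Wounding with forceps changed 11369 of 21223 genes (6101 higher and 5268 lower) in WT. Jasmonate genes rose here too, as 25 of 25 rose and 0 fell (25 and 0 adjusted over the list alone, median 5.56, adjusted p = 0.022 with an estimated correlation), with the allene oxide cyclases AOC2 (AT3G25770, 3.76 ± 0.08) and AOC1 (AT3G25760, 5.56 ± 0.10) of jasmonate synthesis first. Detoxification genes rose too, GSTU4 (AT2G29460, 6.40 ± 0.22) among them. Of the list's genes 18 of 19 rose and 0 fell (18 and 0 adjusted over the list alone, median 1.27, adjusted p = 0.031 with an estimated correlation). For indole defence genes 17 of 18 rose and 0 fell (17 and 0 adjusted over the list alone, median 1.85, adjusted p = 0.055 with an estimated correlation), with CYP79B3 (AT2G22330, 2.36 ± 0.08). In the flg22 list 757 of 967 rose and 17 fell (771 and 17 adjusted over the list alone, median 1.49, p = 0.036 with an estimated correlation). PYL6 (-2.86 ± 0.13) fell most.

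UVB changed 8605 of 21109 genes (4077 higher and 4528 lower) in WT. Light protection genes ELIP1 (AT3G22840, 2.19 ± 0.13) and ELIP2 (AT4G14690, 3.00 ± 0.21) and the light regulator HY5 (AT5G11260, 1.43 ± 0.11) rose, while in the whole UVB and flavonoid list 10 of 16 rose and 2 fell (10 and 2 adjusted over the list alone, median 0.64, adjusted p = 0.20 with an estimated correlation). In the flg22 list 693 of 883 rose and 21 fell (711 and 25 adjusted over the list alone, median 1.11, p = 0.0014 with an estimated correlation). Thalianol synthase THAS1 (AT5G48010, -3.29 ± 0.24) and MRN1 (-3.08 ± 0.24), both of root triterpene synthesis, fell. H2O2 (10 mM) changed 8601 of 21543 genes (4536 higher and 4065 lower). Heat shock genes showed the largest rises, with HSP17.6A (AT5G12030, 11.48 ± 0.22), HSP17.6II (AT5G12020, 10.17 ± 0.16) and the chaperone HSP101 (AT1G74310, 5.33 ± 0.10). In this list 16 of 16 rose and 0 fell (16 and 0 adjusted over the list alone, median 5.35, adjusted p = 0.040 with an estimated correlation). Glutathione transferases such as GSTF8 (AT2G47730, 2.16 ± 0.06) rose within the detoxification list, of which 17 of 19 rose and 0 fell (17 and 0 adjusted over the list alone, median 2.04, adjusted p = 0.019 with an estimated correlation). For the flg22 list 762 of 862 rose and 3 fell (774 and 4 adjusted over the list alone, median 1.71, p = 0.0022 with an estimated correlation). UVB and H2O2 have no unstimulated mutant libraries, so the mutants were compared with WT after the stimulus alone.

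Across genes, responses of sets that share no library were correlated, genes not being independent replicates. The 30 min responses to 100 nM and to 2 nM flg22 gave r = 0.90 and rho = 0.64, and the pep3 and 1 h flg22 responses r = 0.86 and rho = 0.73. Methyl jasmonate and wounding gave r = 0.61 (rho = 0.30), flg22 at 30 min and H2O2 r = 0.69 (rho = 0.54), and flg22 at 30 min and UVB r = 0.66 (rho = 0.39), while abscisic acid and flg22 at 30 min gave r = -0.014 (rho = -0.031). In the first pair 3354 genes rose in both, against 1032.4 for independent calls, and 2331 fell in both, against 913.9. In all 30 pairs were computed.

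Without a stimulus, impk36 differed from WT in 755 of 21211 genes (243 higher and 512 lower) of set B1. Lower genes included the pattern-triggered WRKY33 (-1.13 ± 0.14), IGMT1 (AT1G21100, -1.44 ± 0.13) of indole glucosinolate synthesis, CER1 (AT1G02205, -1.95 ± 0.19) of wax synthesis and AIR1 (AT4G12550, -2.25 ± 0.20). In the flg22 list 8 of 927 were higher and 125 were lower (13 and 189 adjusted over the list alone, median -0.20, p = 0.028 with an estimated correlation). The floral organ gene SEP3 (AT1G24260, -1.23 ± 0.15) was the 1 of 5 floral markers that passed. The B1 count was 432 and 501 without replicates 1 and 2 of WT, and 400 and 406 without replicates 2 and 3 of impk36. In set B2 the same lines differed in 6655 of 21223 genes (3127 higher and 3528 lower). The flg22 list did not pass in B2 with an estimated correlation. There transcripts of the chloroplast genome were higher, with ATCG00020 (2.796 ± 0.30) for the psbA locus first. All 12 impk36 libraries of B2 had 13.4 to 16.5% of alignments not unique and 0.20 to 0.33% of counts from organelle genes, against 6.06 to 7.63% and 0.050 to 0.092% in 23 of the other 24 and 12.8% and 0.15% in WT wounding replicate 1. The line and this property of its libraries cannot be told apart in B2. Auxin and growth genes were higher, as 10 of 14 were higher and 3 were lower (10 and 3 adjusted over the list alone, median 1.02, adjusted p = 0.021 with an estimated correlation), and so was the expansin EXPA8 (AT2G40610, 2.16 ± 0.17), while GMI1 (AT5G24280, -1.86 ± 0.18) and NAC044 (AT3G01600, -1.80 ± 0.14), known from DNA damage responses, were lower. Fold changes of the 2 sets correlated at r = 0.14 across genes (rho = -0.0056), and at r = -0.013 over genes with a mean of at least 5 CPM.

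impk4 differed from WT in 17 of 21211 genes (10 higher and 7 lower) in set B1, where the genes included MPK4, EHD1, ATM1 and MEE29 (AT2G35340, -0.76 ± 0.10). The B1 count was 11 without replicate 1 of WT, 10 with the compared libraries fitted alone and 53 with DESeq2. Set B2 gave 3527 of 21223 genes (1779 higher and 1748 lower), and 2090 genes without replicate 2 of WT. EXPA8 (2.06 ± 0.17) was high, in a list of which 11 of 14 were higher and 1 were lower (11 and 1 adjusted over the list alone, median 0.88, adjusted p = 0.00037 with an estimated correlation), and NAC044 (-1.68 ± 0.13) was low. Both mutants were compared with the same 3 WT libraries, so a likeness between them may come from these. Across genes the 2 sets correlated at r = 0.027 (rho = -0.098). Over the 3510 genes called in B2 and tested in B1, r was 0.087. Interactions in set B2 subtract these baseline differences, so counts of mutants against WT among stimulated libraries alone are given beside them.

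The interaction asks whether a mutant responded to a stimulus differently from WT. With pep3, the response of impk36 differed in 3423 of 21211 genes (1625 higher and 1798 lower). Indole and camalexin genes fell short of WT, as 1 of 17 were higher and 12 were lower (1 and 12 adjusted over the list alone, median -1.34, adjusted p = 0.0037 with an estimated correlation), with GGP1 (AT4G30530, -2.29 ± 0.15), ASA1 (-1.60 ± 0.12) and PAD3 (AT3G26830, -4.64 ± 0.49), the last enzyme of camalexin synthesis. Detoxification genes did likewise, GSTF7 (AT1G02920, -2.37 ± 0.17) first. Of the whole list 1 of 18 were higher and 9 were lower (1 and 9 adjusted over the list alone, median -0.65, adjusted p = 0.0037 with an estimated correlation). Jasmonate genes included JAZ6 (AT1G72450, -2.14 ± 0.20) and AOC1 (-2.45 ± 0.28), and of that list 0 of 25 were higher and 13 were lower (0 and 16 adjusted over the list alone, median -0.86, adjusted p = 0.34 with an estimated correlation). Some immune regulators overshot WT, for example EDS1 (AT3G48090, 1.35 ± 0.12), WRKY22 (2.13 ± 0.23) and CBP60G (1.85 ± 0.29), although EDS5 (AT4G39030, -1.97 ± 0.17), the salicylic acid exporter, was short of it. In the flg22 list 175 of 927 were higher and 211 were lower (209 and 235 adjusted over the list alone, median -0.06, p = 0.53 with an estimated correlation), and among pep3 libraries alone 205 were higher and 430 lower (median -0.30, p = 0.083 with an estimated correlation). Replicate 3 of impk36 with pep3 had 42.4% of alignments not unique, the highest of all libraries. Among pep3 libraries alone 7223 genes differed.

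After flg22, impk36 differed from the WT response in 1399 of 21223 genes (521 higher and 878 lower) at 30 min. More members of the flg22 list were short of WT than above it, as 30 of 967 were higher and 328 were lower (40 and 419 adjusted over the list alone, median -0.59, p = 0.023 with an estimated correlation). YLS9 (AT2G35980, -2.74 ± 0.20) and RBOHD (-0.90 ± 0.12) stood for the pattern-triggered genes, of which 0 of 17 were higher and 10 were lower (0 and 10 adjusted over the list alone, median -0.83, adjusted p = 0.44 with an estimated correlation). At 1 h 3211 of 21223 genes (1756 higher and 1455 lower) differed, and 267 of 967 were higher and 214 were lower (302 and 243 adjusted over the list alone, median 0.14, p = 0.94 with an estimated correlation) in the flg22 list. Among stimulated libraries alone the direction of that list turned, with 340 higher and 443 lower (median -0.15, p = 0.70 with an estimated correlation). Early factors were above the WT response, with ERF5 (2.73 ± 0.18) and CZF1 (AT2G40140, 1.66 ± 0.12). Of the list's genes 12 of 22 were higher and 1 were lower (12 and 1 adjusted over the list alone, median 0.81, adjusted p = 0.27 with an estimated correlation). TCH4 (AT5G57560, 4.44 ± 0.26), a cell wall enzyme induced by touch, and PHI-1 (4.08 ± 0.22) were above it as well. The interaction of MPK3 (1.69 ± 0.15) was positive from a low start, at 14.9 ± 0.899 CPM in unstimulated impk36 and 61.9 ± 6.16 in WT, and at 1 h its level was 220.1 ± 25.5 against 282.7 ± 25.3. Indole defence genes were below, IGMT1 (-3.01 ± 0.18) and PAD3 (-4.56 ± 0.39) among them, where 0 of 18 were higher and 10 were lower (1 and 10 adjusted over the list alone, median -0.85, adjusted p = 0.10 with an estimated correlation), as was FRK1 (AT2G19190, -3.49 ± 0.45), a kinase gene marking flg22 responses. Stimulated libraries alone gave 7640 genes at 30 min and 9999 at 1 h.

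The pep3 response of impk4 differed from WT in 149 of 21211 genes (26 higher and 123 lower). The flg22 list was short of WT by a small step, as 0 of 927 were higher and 68 were lower (2 and 227 adjusted over the list alone, median -0.36, p = 0.00019 with an estimated correlation). MAPKKK5 (AT5G66850, -0.61 ± 0.11), WRKY29 (AT4G23550, -0.59 ± 0.12) and EDS1 (-0.64 ± 0.13) were lower, and IAA29 (AT4G32280, 1.79 ± 0.42) of auxin signalling was higher. The count was 83, 84 and 87 without unstimulated WT replicates 1, 2 and 3, 85, 60 and 95 without those of impk4, and 69, 88 and 409 without impk4 pep3 replicates 1, 2 and 3. IAA29 lost its call without any 1 of 9 libraries (all but WT pep3 replicate 3 and impk4 pep3 replicates 1 and 2), at 1.38 to 1.89. WRKY29 lost it without WT replicate 1, impk4 replicate 2 or impk4 pep3 replicate 1, at -0.55 to -0.50. When the compared libraries were fitted alone, none of these 4 genes was called and the count was 13. After flg22, 681 of 21223 genes (208 higher and 473 lower) differed at 30 min, with DMP1 (AT3G21520, -5.78 ± 0.80) and the glutamate receptor homologue GLR2.8 (AT2G29110, -5.72 ± 0.93) lower and WRKY18 (AT4G31800, 1.27 ± 0.16) higher, and 20 of 967 were higher and 190 were lower (41 and 261 adjusted over the list alone, median -0.36, p = 0.071 with an estimated correlation) in the flg22 list. At 1 h 2218 of 21223 genes (1242 higher and 976 lower) differed, DMP1 (-5.41 ± 0.78) and LACS3 (AT1G64400, -2.44 ± 0.12) lower, and in the flg22 list 41 of 967 were higher and 176 were lower (48 and 213 adjusted over the list alone, median -0.31, p = 0.23 with an estimated correlation). Stimulated libraries alone gave 1215 genes with pep3, 5433 with flg22 at 30 min and 8103 at 1 h. At 30 min 67 of the flg22 list were higher and 540 lower among them (median -0.39, p = 0.021 with an estimated correlation). At 1 h 79 were higher and 524 lower (median -0.35, p = 0.074 with an estimated correlation).

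**Figure D3:**
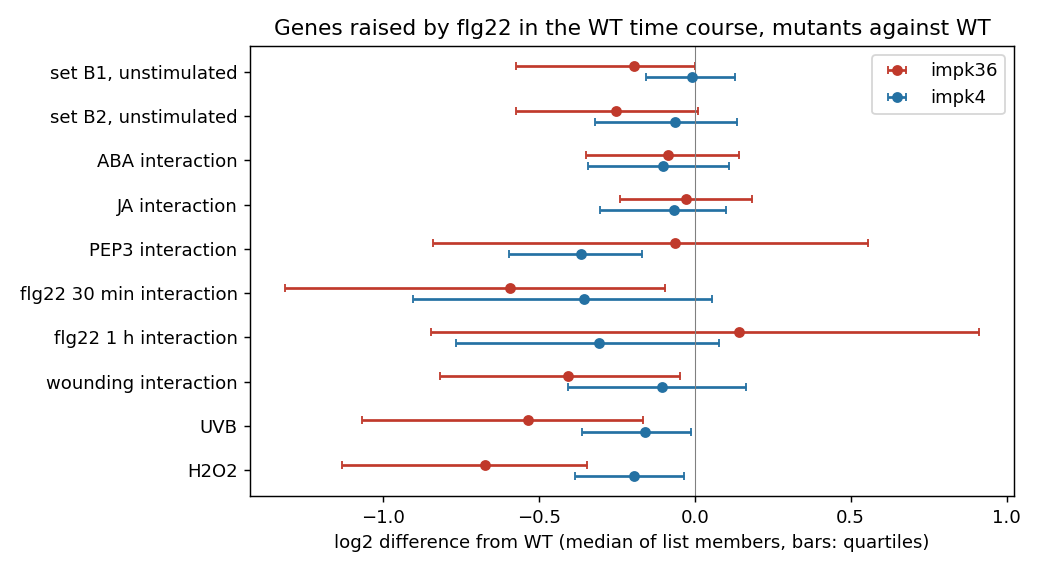
Log2 difference between each mutant and WT over the genes of the flg22 list (median with quartiles), without a stimulus, as interaction, or after UVB or H2O2. The median was -0.59 for the impk36 interaction with flg22 at 30 min and -0.36 for that of impk4 with pep3.

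Abscisic acid and methyl jasmonate responses differed little between lines. edgeR called 0 genes for abscisic acid in either mutant, with 1035 genes for impk36 and 1065 for impk4 at an unadjusted p under 0.05, and DESeq2 called 6 and 6. With the compared libraries fitted alone it was 4 in impk4. Methyl jasmonate gave 3 genes in impk36, IGMT1 (1.15 ± 0.18), BGLU18 (AT1G52400, 1.09 ± 0.17) and ADS1 (AT4G29140, -1.14 ± 0.13), and 1 in impk4, TCH3 (-0.89 ± 0.15), a calmodulin-like gene. DESeq2 called 8 and 4, and edgeR 5 and 0 with the compared libraries fitted alone. With jasmonate IGMT1 stood at 19.0 ± 1.28 CPM in impk36 and 23.2 ± 0.664 in WT, and without a stimulus at 9.86 ± 1.53 and 26.6 ± 3.67, so its positive interaction starts from a lower level. IGMT1 lost its call without unstimulated impk36 replicate 3 (1.04). TCH3 lost it without unstimulated WT replicates 1 or 2, WT jasmonate replicate 2, unstimulated impk4 replicates 1 or 2, or impk4 jasmonate replicates 1 or 2 (-0.89 to -0.77), or when the compared libraries were fitted alone (-0.89, adjusted p = 0.60), and the impk4 count was 4 without unstimulated impk4 replicate 3 and 2 without impk4 jasmonate replicate 3. With abscisic acid, edgeR called 1 gene in impk36 without its unstimulated replicate 1 or 3, and 1 in impk4 without its unstimulated replicate 3. Among stimulated libraries alone impk36 differed from WT in 844 genes with abscisic acid and 382 with methyl jasmonate, and impk4 in 55 and 24. Wounding gave 1154 of 21223 genes (356 higher and 798 lower) for impk36, FRK1 (-2.12 ± 0.46) and RD26 (AT4G27410, -1.40 ± 0.20) lower and PYL6 (1.42 ± 0.19) higher, while 9 of 967 were higher and 160 were lower (20 and 242 adjusted over the list alone, median -0.41, p = 0.15 with an estimated correlation) in the flg22 list. With the compared libraries fitted alone the count was 1780. For impk4 1700 of 21223 genes (777 higher and 923 lower) differed, with LHCA4 (AT3G47470, -0.79 ± 0.11) first among photosynthesis genes, of which 1 of 19 were higher and 8 were lower (1 and 12 adjusted over the list alone, median -0.31, adjusted p = 0.19 with an estimated correlation). Wounded libraries alone gave 8758 genes for impk36, with 14 of the flg22 list higher and 626 lower (median -0.65, p = 0.049 with an estimated correlation), and 512 for impk4.

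After UVB, impk36 differed from WT in 2054 of 21109 genes (766 higher and 1288 lower). The flg22 list was low, as 19 of 883 were higher and 476 were lower (36 and 573 adjusted over the list alone, median -0.53, p = 0.0013 with an estimated correlation). PP2-B14 (AT1G56250, -6.18 ± 0.29) and the indole glucosinolate genes IGMT2 (-5.74 ± 0.31) and CYP81F2 (AT5G57220, -3.98 ± 0.24) were among the lowest, and in the indole defence list 1 of 18 were higher and 9 were lower (1 and 12 adjusted over the list alone, median -0.56, adjusted p = 0.13 with an estimated correlation). impk4 differed in 147 of 21109 genes (62 higher and 85 lower), and in the flg22 list 3 of 883 were higher and 35 were lower (13 and 135 adjusted over the list alone, median -0.16, p = 0.031 with an estimated correlation). The impk36 count was 1347 without its replicate 2, and for impk4 it was 36 and 87 without WT replicates 1 and 2, and 26 and 18 without impk4 replicates 2 and 3. With replicate number as a block, the impk4 count was 292, and with DESeq2 331. After H2O2, impk36 differed from WT in 2377 of 21543 genes (649 higher and 1728 lower). GSTU12 (AT1G69920, -6.40 ± 0.22), ZAT11 (AT2G37430, -4.54 ± 0.18) and WRKY30 (AT5G24110, -4.22 ± 0.30) were lowest, WRKY33 (-2.24 ± 0.11) was low, and 5 of 862 were higher and 540 were lower (16 and 615 adjusted over the list alone, median -0.67, p = 0.0019 with an estimated correlation) in the flg22 list. Early factors such as CZF1 (-0.84 ± 0.06) counted 0 of 20 higher and 11 lower (0 and 14 adjusted over the list alone), with adjusted p = 0.13 with an estimated correlation. impk4 differed in 256 of 21543 genes (79 higher and 177 lower), WRKY53 (-0.92 ± 0.16) among the lower, while 2 of 862 were higher and 66 were lower (6 and 221 adjusted over the list alone, median -0.19, p = 0.035 with an estimated correlation) in the flg22 list. The impk36 count was 1459 without WT replicate 2 and likewise 1459 without impk36 replicate 1. For impk4 it was 86, 52 and 484 without WT replicates 1, 2 and 3, and 57, 422 and 54 without those of impk4, 570 with the compared libraries fitted alone and 707 with DESeq2, and WRKY53 lost its call without impk4 replicate 1 (-0.93) or 3 (-0.87).

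Adult impk4 shoots were compared with their mock at each time after the spray. The adult set held no WT shoots, so effects of the inhibitor that do not depend on the line cannot be told apart here. At 3 h 58 of 20806 genes (54 higher and 4 lower) differed, led by MAKR6 (2.94 ± 0.14), the growth genes SAUR24 (AT5G18080, 1.54 ± 0.16) and SAUR20 (AT5G18020, 1.46 ± 0.16) of the auxin-responsive SAUR family, and HAT2 (AT5G47370, 1.45 ± 0.13), an auxin-induced homeobox gene. At 6 h 1266 of 20806 genes (636 higher and 630 lower) differed, MAKR6 (1.87 ± 0.16) and the cold and drought gene KIN1 (AT5G15960, 1.16 ± 0.20) higher, and the kinesins POK2 (AT3G19050, -1.42 ± 0.36), POK1 (AT3G17360, -1.30 ± 0.30) and HIK (AT1G18370, -1.01 ± 0.26) of cell division lower. The 3 h count was 37, 30 and 30 without mock replicates 1, 2 and 3, and 26 and 27 without treated replicates 1 and 3. At 6 h it was 252 and 108 without mock replicates 2 and 3, and 41 and 679 without treated replicates 1 and 2. With the compared libraries fitted alone the counts were 119 and 2428 at 3 and 6 h, and with DESeq2 112 and 1939. POK2 and HIK lost their calls without any of these 4 libraries (POK2 -1.55 to -1.27, HIK -1.05 to -0.89). POK1 lost it without mock replicate 3 (-1.13) or treated replicate 1 (-1.07), and KIN1 without treated replicate 1 (0.91). Depth was similar throughout the adult set, at 18.9 to 29.3 M counts.

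At 12 h 2953 of 20806 genes (1765 higher and 1188 lower) differed from mock and at 24 h 5250 of 20806 genes (2860 higher and 2390 lower). At 24 h salicylic acid genes were high, with ALD1 (AT2G13810, 5.49 ± 0.50), which makes the systemic resistance signal pipecolic acid, NIMIN1 (AT1G02450, 4.02 ± 0.39) and WRKY70 (2.795 ± 0.31). In this list 15 of 23 were higher and 1 were lower (17 and 1 adjusted over the list alone, median 1.16, adjusted p = 0.23 with an estimated correlation). The defensin PDF1.2 (AT5G44420, -8.43 ± 1.29) was low. In the jasmonate list 0 of 24 were higher and 11 were lower (0 and 18 adjusted over the list alone, median -2.14, adjusted p = 0.60 with an estimated correlation), but replicate 1 of the 24 h mock stood apart from replicates 2 and 3 (chi-square per gene of 53.4 and 68.3, against 14.5 between those). Without it edgeR called 0 of the 24, with 1 higher and 0 lower at an unadjusted p under 0.05, and DESeq2 called 1 higher and 0 lower. The median was then -0.36, so the lower calls of this list rest on that library. JAZ6 (-1.73 ± 0.53) lost its call without mock replicate 1 (-0.99) or treated replicates 1, 2 or 3 (-1.73 to -1.72), or when the compared libraries were fitted alone (-1.71, adjusted p = 0.18). The 24 h count was 3198 with the compared libraries fitted alone. The 12 h count was 1636 without mock replicate 1, and 1441 and 1752 without treated replicates 1 and 3. Among 12 h genes those of the clock were high, PRR7 (AT5G02810, 4.18 ± 0.12) and GI (AT1G22770, 5.21 ± 0.15) first. Of the whole list 9 of 13 were higher and 0 were lower (9 and 1 adjusted over the list alone, median 0.76, adjusted p = 0.021 with an estimated correlation). In the same libraries root markers such as EXPA7 (AT1G12560, 5.29 ± 0.85) and the floral gene SEP3 (6.41 ± 0.45) were raised at 12 h, and of the root markers 4 of 9 were higher and 0 were lower (4 and 1 adjusted over the list alone, median 1.07, adjusted p = 0.26 with an estimated correlation). Transcripts of 63 genes near 0 in the other impk4 adult libraries stood at a median of 7.04% of their seedling level (quartiles 5.97 and 8.95%) in the 6 libraries treated for 12 and 24 h. An alternative chosen after the data were seen took genes whose seedling level does not exceed the mock level. Of these 773 of 6298 differed at 12 h (282 higher and 491 lower) and 2236 of 6603 at 24 h (543 higher and 1693 lower). This choice uses the mock level that also enters the fold change, and seedling counts would lower such genes. It thus favours lower calls. Among these genes 10 of 17 of the salicylic acid list were higher and 1 lower at 24 h. Of the 13 clock genes only 2 were among those genes at 12 h, neither called by edgeR, so the rise of the clock list lay in genes that seedlings hold above the mock level.

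**Figure D4:**
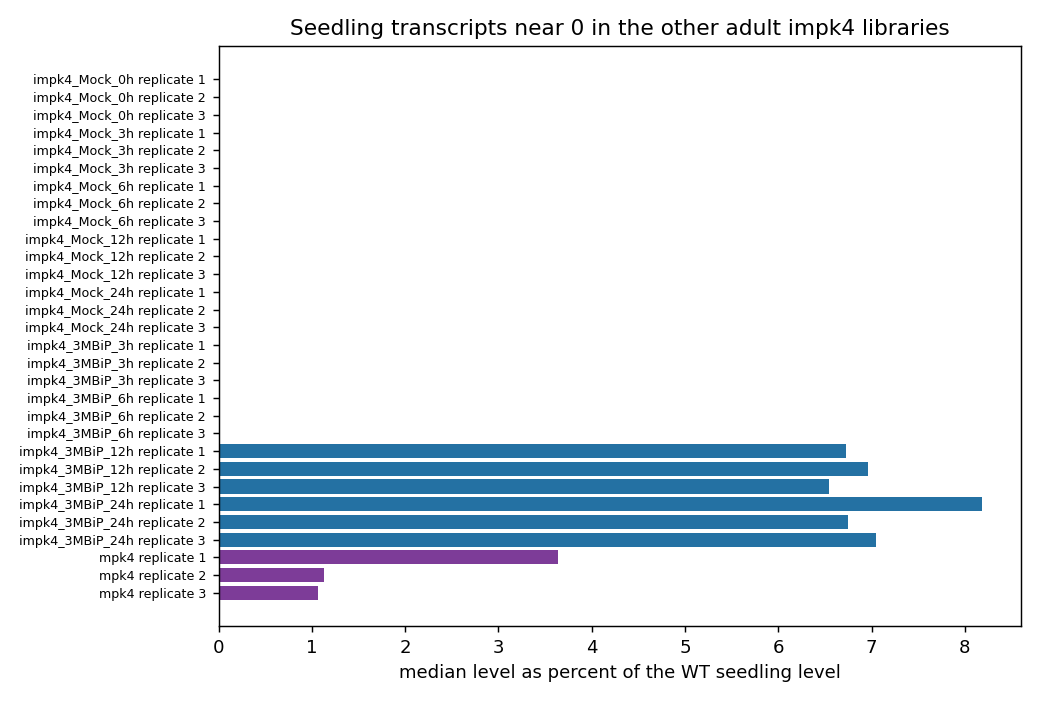
Median level of 63 genes in each adult library, as a percentage of their level in unstimulated WT seedlings of set B4. It was 6.54 to 8.19% in the 6 libraries treated for 12 and 24 h, 0 in the other impk4 libraries, and 3.64, 1.13 and 1.06% in mpk4.

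mpk4 shoots differed from untreated impk4 shoots in 16269 of 20806 genes (9473 higher and 6796 lower). Without adult WT shoots, traits of mpk4 and traits of the impk4 line cannot be told apart in this comparison. EHD1, for example, averaged 58.1 CPM in mpk4, against at most 2.70 in any impk4 mock library. The salicylic acid marker PR1 (AT2G14610, 9.09 ± 0.51) was high at 583.8 ± 106 CPM against 1.08 ± 1.23, and PR5 (AT1G75040, 5.97 ± 0.35) followed, in a list of which 22 of 23 were higher and 1 were lower (22 and 1 adjusted over the list alone, median 3.09, adjusted p = 0.47 with an estimated correlation). Photosynthesis genes were all low, LHCB2.1 (-6.19 ± 0.12) first. Of the list's genes 0 of 19 were higher and 19 were lower (0 and 19 adjusted over the list alone, median -3.16, adjusted p = 0.21 with an estimated correlation). Pattern-triggered genes were high, among them WRKY17 (AT2G24570, 2.75 ± 0.13) and FRK1 (5.46 ± 0.27). In this list 14 of 18 were higher and 1 were lower (14 and 1 adjusted over the list alone, median 2.52, adjusted p = 0.47 with an estimated correlation). Clock genes parted widely, LHY (AT1G01060, -8.46 ± 0.18) and CCA1 (AT2G46830, -8.48 ± 0.19) low and ELF4 (AT2G40080, 8.15 ± 0.20) high. Of the whole list 8 of 13 were higher and 5 were lower (8 and 5 adjusted over the list alone, median 3.94, adjusted p = 0.67 with an estimated correlation). A comparison with the 6 h mock was chosen after the data were seen. That mock was sprayed with 1% DMSO, while mpk4 was untreated. Against it 14878 genes differed (7621 higher and 7257 lower), and 4 of 13 clock genes were higher and 3 lower. There 22 of 23 salicylic acid genes were higher (median 4.53) and all 19 photosynthesis genes lower (median -2.10). Adjusted p was 0.21 for each list with an estimated correlation. Root markers were higher there too, 8 of 9 (median 2.92, adjusted p = 0.53 with an estimated correlation). Several of them were low and uneven in mpk4, with EXPA7 at 0.302 ± 0.281, SHV2 at 0.154 ± 0.146 and CASP1 at 1.63 ± 2.3 CPM. The root marker SCR stood at 40.9 ± 1.3 CPM in mpk4, but also at 45.3 ± 2.26 in untreated impk4 and 33.3 ± 0.864 in the 6 h mock. Its level thus does not mark root transcripts in mpk4. Senescence genes were higher as well, 10 of 11 (median 4.33, adjusted p = 0.21 with an estimated correlation). Replicate 2 of untreated impk4 stood apart from replicates 1 and 3 (chi-square per gene of 43.3 and 30.4, against 20.0 between those). Against 0 h without it, 22 salicylic acid genes were higher and all 19 photosynthesis genes lower. Senescence genes then counted 5 of 11 higher and 3 lower (median 0.47), so their rise depended on the mock time. Across genes the mpk4 change correlated with that of 3, 6, 12 and 24 h of inhibitor at r = -0.22, -0.078, 0.31 and 0.47 (rho = -0.33, -0.20, -0.040 and 0.37). Over genes of at least 5 CPM r was -0.35, -0.24, 0.018 and 0.31. For 24 h, mpk4 against the 6 h mock gave r = 0.51 over all genes. Over the 6603 genes not above the mock level in seedlings it gave 0.28, and mpk4 against 0 h gave 0.12.

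Mock shoots differed among the 5 times in 17573 of 20806 genes by edgeR's F test. The morning gene CCA1 fell from 414.7 ± 42.5 CPM at 0 h to 0.865 ± 0.0966 at 6 h and stood at 175.6 ± 9.03 at 24 h. The evening gene TOC1 (AT5G61380) ran the other way, from 13.3 ± 5.92 at 0 h to 223.9 ± 3.74 at 6 h and 9.34 ± 0.592 at 24 h. Over the 13 clock genes, mpk4 lay closest to the 6 h mock, at a root mean square log2 distance of 0.44, against 5.74 from 0 h.

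**Figure D5:**
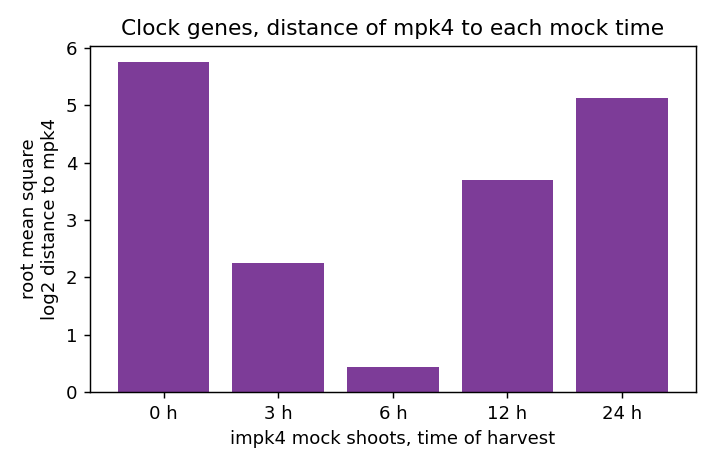
Root mean square log2 distance of mpk4 from each mock time over 13 clock genes. The distance was 5.74 at 0 h and 0.44 at 6 h.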

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

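The 2 tests on seedling counts in adult libraries, the comparison of the clock with random lists, the overlap with the flg22 list of genes lower in impk36, the splits by pairs and all added alternatives were chosen after the result was seen. The other tests were set before theirs. Differences between lines in the response to a stimulus brought 10 results here, each an interaction tested over all genes. They were 3 genes with jasmonate in impk36 and 1 in impk4, 3423 and 149 with pep3, 1399 and 681 with flg22 at 30 min, 3211 and 2218 at 1 h, and 1154 and 1700 with wounding.

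Outside the gene counts, replicate 3 of impk36 with pep3 had 42.38% of alignments not unique, and without it the pep3 interaction of impk36 held 3158 genes.

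Comparisons of 3 libraries with 3 allow 10 splits, too few for a share under 0.05. The numbers of splits with as many genes, the real one included, were 10 for abscisic acid in each mutant, 9 and 2 for jasmonate in impk36 and impk4, 2 for pep3 in impk4 and 1 in each other comparison. The real count and the highest of the other splits were 3423 and 60 for pep3 in impk36, 149 and 395 in impk4, 1399 and 258 and then 681 and 30 for flg22 at 30 min, 3211 and 406 and then 2218 and 123 at 1 h, and 1154 and 230 and then 1700 and 1439 for wounding. For jasmonate they were 3 and 8 in impk36 and 1 and 1 in impk4, and for abscisic acid 0 and 4, and 0 and 1. The 395 came from exchanging impk4 pep3 replicate 2 with WT pep3 replicate 3, and the next highest was 3, which points to a structure of these libraries whose source was not tested. Splits of interactions exchanged stimulated libraries alone, so the baseline difference between lines stayed in them. For wounding in impk4 the 9 other splits gave 843 to 1439 genes. Where the baselines differ, such splits are not free of that difference, and its source for impk4 in B2 remains open. In the 4 planned comparisons taken as paired, other splits that part as many pairs gave 0 genes, and those that part fewer gave at most 69 and 0 for impk36 at baseline in B2 and with H2O2, 33 for impk4 with UVB and 0 for adults at 6 h.

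For responses of WT the real counts and the highest others were 1834 and 0 (inhibitor), 6454 and 0 (abscisic acid), 6827 and 0 (jasmonate), 13261 and 0 (pep3), 9162 and 1 and then 12818 and 3 (flg22 at 30 min and 1 h), 11369 and 0 (wounding), 8605 and 0 (UVB) and 8601 and 0 (H2O2). For lines they were 755 and 0 (impk36) and 17 and 0 (impk4) at baseline in B1, 6655 and 69 and then 3527 and 7 in B2, 2054 and 2 and then 147 and 33 with UVB, and 2377 and 0 and then 256 and 0 with H2O2. In adults they were 58 and 0, 1266 and 0, 2953 and 0 and 5250 and 5 at 3, 6, 12 and 24 h, and 16269 and 8 for mpk4. For the mock times 1 of 100 splits, the real one, gave 17573 genes and the highest other 13821. A share of 1 in 100 is the smallest that these splits can give.

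In adult shoots treated for 12 and 24 h the root markers EXPA7, EXPA18, CASP1 and SHV2 and the floral gene SEP3 rose. The floral gene AG did not (0.597 CPM against 0.693 in mock at 12 h, 1.898 against 2.339 at 24 h). AG stood at 0.526 CPM in unstimulated WT seedlings of B4, so seedling counts would not raise it. The root markers SCR, SHR, GL2 and NRT2:1 did not rise at 12 h (38.3, 14.9, 17.95 and 1.11 CPM against 43.3, 15.1, 18.1 and 1.53 in mock). Over 63 genes at most 0.3 CPM in the other adult impk4 libraries and at least 20 CPM in seedlings, the levels in the 6 libraries followed the seedling level with a correlation of 0.9096, at a median of 7.036% of it (quartiles 5.967 and 8.947, per library 6.54 to 8.19%). The mpk4 libraries, which did not choose these genes, held 3.64, 1.13 and 1.06% of it. EHD1, nearly silent in impk4, reached 6.5152 CPM in the lowest of the 6 libraries against 2.698 in the highest mock library, which argues against roots of the impk4 plants themselves. Counts from seedlings that carry EHD1 in these 6 libraries are the candidate source that remains open, while plants of another line and an effect of the inhibitor were not tested. Among genes whose seedling level does not exceed the mock level, 773 of 6298 (282 higher and 491 lower) differed at 12 h. At 24 h 2236 of 6603 did (543 higher and 1693 lower). The choice of these genes uses the mock level that also enters the fold change, and seedling counts would lower such genes. It thus favours lower calls, which are not freed of seedling counts.

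The count of baseline differences between impk4 and WT was 17 in B1 and 3527 in B2. A smaller spread or deeper libraries in B2 would leave fold changes alike, but over 3510 genes called in B2 and tested in both sets the correlation was 0.0873, with a median absolute log2 fold change of 0.3496 in B2 and 0.0862 in B1. Untreated libraries of B2 that stand apart would leave no difference among stimulated ones, but the correlation with the flg22 30 min libraries was 0.8093, with 0.7716 at 1 h and 0.379 with wounding. Wounded libraries alone gave 512 genes, against 5433 and 8103 with flg22, which argues against a difference that spans all libraries of B2 alike. What sets the unstimulated and flg22 libraries of impk4 apart remains open, and neither growth nor a biological effect of MPK4 seen in B2 alone was tested. The interactions subtract this baseline.

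Clock genes separated mpk4 from untreated impk4 shoots. Over the 13 clock genes, mpk4 lay at a root mean square log2 distance of 0.4401 from the 6 h mock, against 5.743, 2.2587, 3.6986 and 5.1179 from the 0, 3, 12 and 24 h mocks. The clock list had a median absolute log2 fold change of 6.2098, at percentile 100 of 10000 random lists of matched expression (their median 0.6851). A harvest of mpk4 at another time of day, near that of the 6 h mock, is the likely candidate explanation, and the labels give no harvest time. An effect of mpk4 on the clock itself was not tested, and against the 6 h mock 14878 genes (7621 higher and 7257 lower) still differed.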

How the results depend on the processing

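The comparisons of mutants with WT among stimulated libraries, mpk4 against the 6 h mock, the restriction to genes not above the mock level in seedlings, and adult lists without a control library that stands apart were chosen after the data were seen. With DESeq2 size factors all 40 counts of genes stayed within 1.5 times the reported one (0.92 to 1.234 times), and the median of all genes moved by at most 0.0344. Without a filter on low counts 39 of 40 did, and the 5 min count of the time course was 734. The cause was not tested for this and the other changes below, except where genes or libraries were left out by construction.

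With DESeq2 itself 30 of 39 counts stayed within 1.5 times. The others were 53 for impk4 at baseline in B1, 6 and 6 for abscisic acid in impk36 and impk4, 8 and 4 for jasmonate, 331 for impk4 with UVB, 707 for impk4 with H2O2, and 112 and 1939 for adults at 3 and 6 h. The F test over mock times was replaced by a likelihood ratio test there. When the compared libraries were fitted alone 30 of 40 stayed within 1.5 times, and the others were 10 for impk4 at baseline in B1, 4 for abscisic acid in impk4, 5 and 0 for jasmonate in impk36 and impk4, 13 for pep3 in impk4, 1780 for wounding in impk36, 570 for impk4 with H2O2, and 119, 2428 and 3198 for adults at 3, 6 and 24 h. This fit has fewer libraries to estimate the spread. With the replicate block 34 of 40 counts stayed within 1.5 times, and the others were 40 for impk4 at baseline in B1, 5 and 0 for jasmonate in impk36 and impk4, 261 for pep3 in impk4, and 292 and 586 for impk4 with UVB and H2O2. In the 4 planned comparisons taken as paired the block also let the pattern-triggered list pass for impk36 with H2O2 (adjusted p = 0.0333 against 0.0598) and changed no other call of a count, named gene or list as reported. Elsewhere not all pairs of the groups compared passed 0.1 and the block is given here alone. In B1, B2 and B3 libraries with the same number still correlated at medians of 0.11, 0.10 and 0.23, against -0.06, -0.08 and -0.11 with different numbers (-0.03 to 0.04 in the other sets with the same). Replicate 3 was also deeper in B1 and B2, at medians of 29.7 and 27.7 M counts against 20.2 and 17.9 M in replicate 1 and 20.0 and 18.9 M in replicate 2, a hint from the data that the labels do not explain.

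Among stimulated libraries alone the mutants differed from WT in 844 and 55 genes with abscisic acid (impk36 and impk4), 382 and 24 with jasmonate, 7223 and 1215 with pep3, 7640 and 5433 with flg22 at 30 min, 9999 and 8103 at 1 h (10386 in impk36 with the replicate block, as these numbers pair), and 8758 and 512 with wounding. Genes not above the mock level in seedlings gave 773 at 12 h and 2236 at 24 h, with fewer genes tested, and mpk4 against the 6 h mock gave 14878.

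Leaving out 1 library at a time gave 39 to 443 genes at 5 min and 1205 to 1936 at 10 min of the time course, where the lone library left was assumed to vary like the others. It gave 1095 to 1590 for the inhibitor in WT, 400 to 663 for impk36 and 11 to 19 for impk4 at baseline in B1, 2090 to 3643 for impk4 at baseline in B2, 0 to 1 for abscisic acid in impk36 and in impk4, 0 to 4 for jasmonate and 60 to 409 for pep3 in impk4. With UVB it gave 1347 to 1906 for impk36 and 18 to 131 for impk4, with H2O2 1459 to 2540 and 52 to 484, and in adults 26 to 66 at 3 h, 41 to 1229 at 6 h and 1441 to 3179 at 12 h. The other comparisons stayed within 1.5 times.

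The flg22 list passed with a preset correlation of 0.01, and not with the estimated one, for the inhibitor in WT (p = 4.754e-09), abscisic acid in impk36 (0.0001068) and impk4 (1.922e-05), jasmonate in impk4 (0.001487), impk36 at baseline in B2 (2.1e-05), flg22 in impk4 at 30 min (5.721e-23) and 1 h (8.942e-11), and wounding in impk36 (1.116e-14). It passed for the inhibitor with the replicate block (0.0437), and at a threshold of 1 it missed for impk4 with UVB (0.05037). Over all lists 255 results passed only with the preset correlation and 515 stayed as they were, 7 passed and 10 failed only with the block, and 3 passed only with DESeq2 size factors.

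Correlations changed by over 0.1 when limited to genes of at least 5 CPM in these cases. They went to -0.3523, -0.2389, 0.0175 and 0.3067 for mpk4 with adults at 3, 6, 12 and 24 h. For wounding with abscisic acid and jasmonate they went to 0.2942 and 0.7083, and for impk36 at baseline in B1 and B2, with a turn of sign, to -0.0134. Abscisic acid with flg22 turned sign by less, from -0.0144 to 0.0169 at 30 min and from -0.0505 to 0.0165 at 1 h. With mpk4 against the 6 h mock over genes not above the mock level in seedlings, the correlation with adults at 24 h was 0.2848. Of 164 values of named genes, none changed sign under these alternatives. All kept their call with DESeq2, DESeq2 size factors and no filter, 6 lost it when the compared libraries were fitted alone and 1, TCH3 with jasmonate in impk4, with the replicate block (-0.89, adjusted p = 0.085), and of the refits without 1 library 37 lost it and 1125 kept it. In simulated data at this depth 70 to 98 of 100 genes changed 1.5-fold were recovered.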

Other observations

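The overlap and the timing hypothesis below came from values already seen, and of their tests the overlap was chosen after its result was seen. Among the genes compared in all 4 seedling sets, 137 differed between impk36 and WT in each set in the same direction, 14 higher and 123 lower, where 0.5294 genes would be expected if the sets were independent. For impk4 there were 7, of which 3 were higher and 4 lower. Of the 123 genes lower in impk36, 61 belonged to the flg22 list (49.59% against 4.15% of the genes compared, 5.1 expected, odds ratio 24.446, Fisher's exact p = 3.87e-51). Genes of a response move together, so this p overstates the evidence. In B3 and B4 the lines were compared after UVB or H2O2 alone, so 2 of the 4 sets measure no unstimulated level. The cause was not tested.

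In the flg22 response at 1 h, members of the flg22 list lay above and below WT in impk36. A response that runs later in impk36 predicts that genes falling between 30 and 60 min in the WT time course lie higher in impk36 and those rising lie lower. Over 967 genes the correlation with that change was -0.5092 (Spearman -0.4877). The 426 falling genes had a median of +0.6499 and the 541 rising genes -0.3081. The same correlation was -0.1436 at 30 min and -0.1999 for pep3 in impk36, and 0.1151, 0.263 and 0.0124 for impk4 at 1 h, at 30 min and with pep3. A later response is thus a hypothesis that may apply to impk36 at 1 h, and a change in the shape of the response would give the same sign.

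AT2G43795 and AT4G01390 overlap the ends of MPK6 and MPK4 in TAIR10.1 (chromosome 2, 18140944 to 18142435; chromosome 4, 570200 to 571595) and rose with these genes in impk36 and impk4. One untreated adult impk4 library, replicate 2, held MPK3 at 418.8 CPM against 160 and 162.7 in the other 2. Between unstimulated seedlings and adult shoots, the floral marker SEP3 stood at 48.4 CPM in seedlings and at 7.64 and 7.70 in adult shoots treated for 12 and 24 h. In the other adult groups it was at or below 0.42 CPM.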
